A study of Homo sapiens with 8 samples.

How the data were processed

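DNA methylation and total RNA were profiled in DU145, LNCaP-FGC, PC3 and RWPE-1, with 1 array per line and assay. Per the labels' protocols, genomic DNA was bisulfite-converted and hybridised to an Illumina HumanMethylation27 beadchip, and biotin-labelled cRNA was hybridised to an Illumina HumanHT-12 beadchip. The authors deposited methylation as beta values, the methylated fraction of signal at each CpG site from 0 to 1, with no signal intensities or detection p-values in the table used here. The authors deposited expression as probe intensities exported from BeadStudio (version 3.1.3, per the series text given in the labels), which were neither background-subtracted nor normalized between arrays, judging from the lowest values of 92.3 to 104 and the different medians of the arrays. A further table deposited by the authors holds log2 expression values that share 1 distribution across the 4 arrays up to 0.01, with a median of 7.37 in each column, so they were quantile normalized; its scale and direction were checked against the raw intensities, with which each column correlated best for its own line (r of 0.9993 to 0.9999, against 0.890 to 0.923 for the best other line). The steps behind that table are not given in the sources used here.

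Samples were grouped by the source named in the labels into cancer lines (n = 3) and the control line (n = 1) for each assay, and table columns were matched to samples by name. The labels name no replicate arrays or cultures. The choices below were made before the data were examined unless stated otherwise.

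Expression intensities were background-corrected with limma's normexp method (offset 50) and quantile normalized on the log2 scale. In the absence of detection p-values, a probe was kept if it exceeded its array's median on at least 1 array. The plan to keep 1 probe per gene could not be followed because the tables pair no probe or site with a gene, and the tables of gene names used here list neither kind of identifier, so all probes were analysed as probes. For the same reason the 20 gene lists fixed in advance, the match of methylation to expression by gene, the removal of sites on the sex chromosomes and the genomic positions of sites were not analysed here. Betas were used as deposited, and 37 sites with a blank beta on any array were left out (5 blanks in LNCaP-FGC, 6 in PC3, 8 in RWPE-1 and 19 in DU145).

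The 3 cancer lines were tested against RWPE-1 with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) on log2 intensity and on log2(beta / (1 - beta)) with betas held at least 0.01 from either limit. The model has 2 residual degrees of freedom, 2.04 prior degrees of freedom for either assay, and assumes that the lone control array varies as the 3 cancer lines do among themselves. Since those are different lines, the test's spread is biological between lines and not the error of repeat arrays, which the data cannot give. Shared differences were counted by size without a test: a difference from RWPE-1 of at least 2-fold, or of at least 0.3 in beta, in the same direction in each of the 3 cancer lines. For each line against RWPE-1 the same sizes were used, with probes above the median on either array. The same counts were made with each line in turn set against the other 3. Sites were also classed as unmethylated (below 0.2), intermediate or methylated (above 0.8). These classes, the shares of sites with room to change by 0.3, the pairwise comparison of lines and the ratios of lower to higher counts with each line set apart were chosen after seeing the data. For overlaps between lines that share the RWPE-1 array, the 4 values of each probe or site were exchanged among the lines at random 100 times.

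The test was tried on simulated data with 200 planted differences. In the expression design (3 against 1, 33622 probes) it recovered 0% of planted log2 differences of 1 and of 2, 24% of those of 4 and 50% of those of 6, with 0 false calls. In the methylation design (3 against 1, 27541 sites) it recovered 0% at planted differences of up to 6 on the log2(beta / (1 - beta)) scale. The 2-fold size rule found 28% of planted log2 differences of 1, 88% of those of 2, 96% of those of 4 and 100% of those of 6 in expression. In the methylation design a size rule of 1 on the log2(beta / (1 - beta)) scale, which is not the beta rule behind the counts, found 26%, 60%, 84% and 92% of planted differences of 1, 2, 4 and 6. Probes and sites without a planted difference that passed the size rules were not counted. How often these rules pass a false difference is therefore unknown.

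Probes and sites to name were the 10 with the largest mean difference in each direction that passed the test and differed in all 3 lines, filled up from the shared differences; as no gene names were at hand, 2 in each direction are given by identifier. The 5 per line set down for single lines are not named, and only their counts are given. Alternatives were no background correction, median scaling, the authors' log2 values, an offset of 16, other filters on dim probes, a variance trend with intensity, size thresholds of 1.5-fold and 4-fold, quantile-normalized betas, wider limits on beta, a test on beta, beta thresholds of 0.2 and 0.5, and leaving out each cancer line. Rescaling each methylation array to a common floor and ceiling was added after seeing the data. Analyses used R 4.3.3 and limma 3.58.1.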

Results

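DNA methylation and gene expression were measured in 4 established human prostate cell lines. DU145, LNCaP-FGC and PC3 are lines grown from metastatic prostate carcinoma, LNCaP-FGC being the androgen-sensitive one of the group. RWPE-1 is a line of non-cancerous prostate epithelium immortalized with a papillomavirus, and it served as the control. Each line was hybridised once to a promoter-weighted methylation array and once to an expression array, giving 8 samples, so no line had a repeat array. Of 27578 CpG sites, 27541 had a methylation level (beta value, the methylated share of the signal at a site) in all 4 lines. The expression array held 48803 probes, of which 33622 were above the median probe on at least 1 array and were tested. Median raw intensities were 178 in DU145, 182 in LNCaP-FGC, 154 in PC3 and 151 in RWPE-1. The comparisons were the 3 cancer lines against RWPE-1, each cancer line against RWPE-1, and the 4 lines with one another. Precision was limited by the number of arrays, and errors given for the cancer lines are the spread between different lines (SD, n = 3).

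The first question was how the methylation landscape of the cancer lines differed from that of RWPE-1. The cancer lines had fewer unmethylated and more methylated sites than the control. Sites with a beta below 0.2 made up 65.3% of the array in RWPE-1, 61.1% in LNCaP-FGC, 59.4% in PC3 and 56.5% in DU145. Sites with a beta above 0.8 made up 13.2% in RWPE-1, 14.7% in LNCaP-FGC, 15.9% in PC3 and 24.2% in DU145. The mean beta was 0.258 in RWPE-1 against 0.288, 0.302 and 0.340 in LNCaP-FGC, PC3 and DU145. A core of 12839 sites (46.6%) was unmethylated in all 4 lines, and 1570 sites (5.70%) were methylated in all 4. The DU145 array had the widest scale. Over the 1570 always-methylated sites its median beta was 0.925 against 0.889 to 0.904 on the other arrays, and over 10916 sites below 0.1 on all arrays it was 0.0151 against 0.0253 to 0.0348.

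Methylation was higher in all 3 cancer lines than in RWPE-1 at 932 sites and lower in all 3 at 108 sites, counting sites at which every cancer line differed by a beta of at least 0.3. These are called shared gains and losses below, by size alone and without a test. The 932 shared gains were large. Their median beta was 0.148 in RWPE-1 and 0.862, 0.833 and 0.834 in DU145, LNCaP-FGC and PC3, and 558 of them (59.9%) were unmethylated in the control. Of 17982 sites with a beta below 0.2 in RWPE-1, 93 were above 0.8 in every cancer line. Of 3645 sites with a beta above 0.8 in RWPE-1, 5 were below 0.2 in every cancer line. The 108 shared losses had a median beta of 0.723 in RWPE-1 and 0.193, 0.0970 and 0.127 in DU145, LNCaP-FGC and PC3, and most of them (72.2%) were intermediate, not methylated, in the control. The largest shared gain was at site cg08089301, with a beta of 0.0211 in RWPE-1 against 0.982 ± 0.00477 (SD, n = 3) in the cancer lines, followed by cg21012874 with 0.0281 against 0.980 ± 0.00591. The largest shared losses were at cg10246520, with 0.915 in RWPE-1 against 0.109 ± 0.0733, and at cg08763351, with 0.873 against 0.0954 ± 0.0677. These 4 sites were picked for the size of their difference, and their adjusted p from limma ran from 0.583 to 0.651.

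No site passed the test across all sites. With limma on log2(beta / (1 - beta)), 0 of 27541 sites reached an adjusted p of 0.05, the lowest adjusted p was 0.583, and 1227 sites had an unadjusted p under 0.05 where 1377 would be expected by chance. Of those 1227 sites, 1118 were higher and 109 lower in the cancer lines. The same model on the beta scale called 70 sites, 68 higher and 2 lower, all of them among the shared gains and losses. That overlap is not separate evidence, since the call and the size rule use the same 4 arrays. Both favour large differences on which the cancer lines agree. All calls on the beta scale lay just under the threshold of 0.05, so a slightly stricter threshold would have called no site. The ratio of shared gains to losses rested on DU145: without it the counts were 1439 gains and 709 losses, against 1641 and 200 without LNCaP-FGC and 1501 and 179 without PC3. Forcing the 4 arrays to a common distribution of betas, which removes any net gain, gave 496 gains and 314 losses, so the share of gains went from 89.6% to 61.2%.

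**Figure D1:**
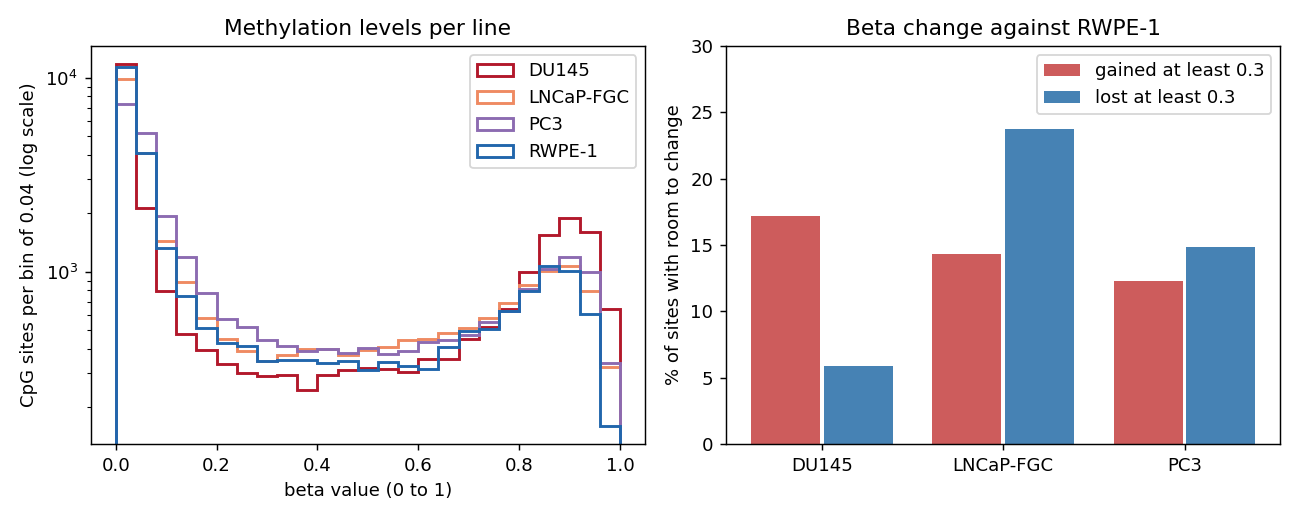
Left, histogram of beta values (x axis, 0 to 1) for each line, as the number of CpG sites per bin on a log axis; right, the share of sites with room to change by 0.3 that gained (red) or lost (blue) at least 0.3 in beta against RWPE-1, 1 array per line. DU145 has the most sites above 0.8, and it lost 5.90% of sites with room where LNCaP-FGC lost 23.7%.

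Each cancer line was also set against RWPE-1 on its own. At least 0.3 in beta was gained at 3873 sites in DU145, 3218 in LNCaP-FGC and 2770 in PC3, and lost at 503, 2023 and 1270 sites. Most RWPE-1 sites are unmethylated and can only gain, so the counts were also set against the sites with room to change. Of 22500 sites that could rise by 0.3, 17.2% gained in DU145, 14.3% in LNCaP-FGC and 12.3% in PC3. Of 8528 sites that could fall by 0.3, 5.90% lost in DU145, 23.7% in LNCaP-FGC and 14.9% in PC3. On that footing LNCaP-FGC and PC3 lost methylation at a larger share of sites than they gained it, and DU145 did the opposite. Among the 3645 sites methylated in RWPE-1, 90.5% were still above 0.8 in DU145, 66.4% in PC3 and 53.7% in LNCaP-FGC. These shares depend on the top of each array's scale, which differed between arrays, and many sites crossed 0.8 by a small shift. A fall of at least 0.3 was rarer, at 3.70% of these sites in DU145, 12.5% in PC3 and 22.3% in LNCaP-FGC. Among the 17982 sites unmethylated in RWPE-1, gains were found at 12.2% in DU145, 12.5% in LNCaP-FGC and 9.68% in PC3. With 1 array per line these differences have no replicate check and carry no p-value. After forcing a common distribution, gains made up 56.2% of the differing sites in DU145 instead of 88.5%, 51.2% in LNCaP-FGC instead of 61.4% and 53.7% in PC3 instead of 68.6%, and the share of sites with room that DU145 gained (8.13%) was then below the share it lost (13.7%).

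Sites that differed in a single cancer line, with the other two within a beta of 0.2 of the control, were mostly gains in DU145, 1001 against 101 losses. LNCaP-FGC had 928 such gains and 788 losses, and PC3 had 402 gains and 290 losses. These counts were not set against the sites with room to change, of which far more could gain than lose. Gains outnumbering losses here therefore does not mean that gains were the more frequent change. Sites gained in 2 cancer lines numbered 1501 for DU145 and LNCaP-FGC, 1641 for DU145 and PC3 and 1439 for LNCaP-FGC and PC3. Because all 3 lines were set against the same RWPE-1 array, such overlaps lie above chance with no shared effect. Independent lists of the same lengths would share 453, 390 and 324 sites, and exchanging the 4 lines at random at each site gave means of 1025, 1027 and 1026 shared gains over 100 draws. Shared losses numbered 179, 200 and 709 for the same 3 pairs, where independent lists would share 36.9, 23.2 and 93.3 sites and exchanged lines gave 1189, 1186 and 1184. Exchanging puts the extremes of every line in the place of RWPE-1, so its means apply only if the 4 lines are alike. They are not what lines without a shared effect would give. Losses lay below the exchanged means in all 3 pairs, so the betas of the 4 arrays were not alike. Without repeat arrays, the exchange cannot tell a difference between the lines from a difference in the scale of their arrays.

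The second question was how gene expression differed between the cancer lines and RWPE-1. At least 2-fold lower intensity in every cancer line was found for 1414 probes and at least 2-fold higher intensity for 794. The median difference was -2.01 on the log2 scale among the probes lower in the cancer lines and 1.79 among those higher. The deposited tables give probe identifiers with no gene. Probe ILMN_2219002, one of the 2 with the largest mean difference among those lower in the cancer lines, had a log2 intensity of 15.32 in RWPE-1 and 6.82 ± 0.74 (SD, n = 3) in the cancer lines. Its raw intensity was 32185 in RWPE-1, 267 in PC3, and 158 in DU145 and 162 in LNCaP-FGC, below the median probe of those arrays. The other, ILMN_1666845, had 15.97 in RWPE-1 and 7.84 ± 1.90 in the cancer lines. Its raw intensity of 62267 in RWPE-1 lay near the top of that array's range, and that of 167 in LNCaP-FGC lay below the median probe. The order of these probes is not settled, since without PC3 their differences were -8.93 and -9.21. The largest difference in the other direction was at probe ILMN_2108735, with 8.33 in RWPE-1 and 14.57 ± 0.47 in the cancer lines, and raw intensities of 361 against 20668 to 35425. Probe ILMN_1730054 had 6.07 in RWPE-1, below the median probe of that array, and 11.27 ± 0.56 in the cancer lines. For probes near background the difference depends on the background correction, and over the alternatives it ranged from 4.27 to 6.20 at ILMN_1730054 and from -7.74 to -9.09 at ILMN_2219002.

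No probe passed the test. With limma on log2 intensity, 0 of 33622 probes reached an adjusted p of 0.05, the lowest adjusted p was 0.0837, and 3092 probes had an unadjusted p under 0.05, 1236 higher and 1856 lower, where 1681 would be expected by chance. Adjusted p values at the 4 named probes were 0.119 for ILMN_2219002, 0.338 for ILMN_1666845, 0.113 for ILMN_2108735 and 0.202 for ILMN_1730054. When limma's variance prior was allowed to follow intensity, 28 probes passed, 27 lower and 1 higher in the cancer lines, and all 28 were among the shared differences. As in methylation, that overlap is not separate evidence, since both come from the same arrays. All probes also share the lone control array, so the number under an unadjusted 0.05 can shift as a whole with that array. Without DU145, LNCaP-FGC or PC3 in turn, the probes higher in the remaining cancer lines numbered 1222, 1529 and 1339.

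Each cancer line was set against RWPE-1 on its own, with 1 array each and no test. At least 2-fold differences were found at 6604 probes in DU145 (3324 higher, 3280 lower), 6131 in LNCaP-FGC (3047 higher, 3084 lower) and 6527 in PC3 (3259 higher, 3268 lower). The balance in PC3 depended on the scaling. With arrays scaled to a common median in place of quantile normalization, PC3 had 4344 higher and 2741 lower probes, 61.3% higher in place of 49.9%. Probes that differed in 1 cancer line alone, with the other two less than 2-fold from the control, were more often higher than lower. They numbered 1134 higher and 737 lower in DU145, 1177 and 632 in LNCaP-FGC and 1171 and 683 in PC3. This lean is not a separate result. Each line's higher and lower totals were nearly equal after quantile normalization, and shared probes were more often lower, so the rest had to lean higher. Probes lower than RWPE-1 in 2 cancer lines numbered 1804 for DU145 and LNCaP-FGC, 2074 for DU145 and PC3 and 1854 for LNCaP-FGC and PC3, where exchanged lines gave 1441, 1440 and 1441 and independent lists would share 301, 319 and 299.8. Probes higher in 2 lines numbered 1339, 1529 and 1222 for the same pairs, where exchanged lines gave 1066, 1069 and 1066 and independent lists would share 301, 322 and 295. As for methylation, the means from exchanged lines apply only if the lines are alike, and they do not measure overlap without a shared effect.

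**Figure D2:**
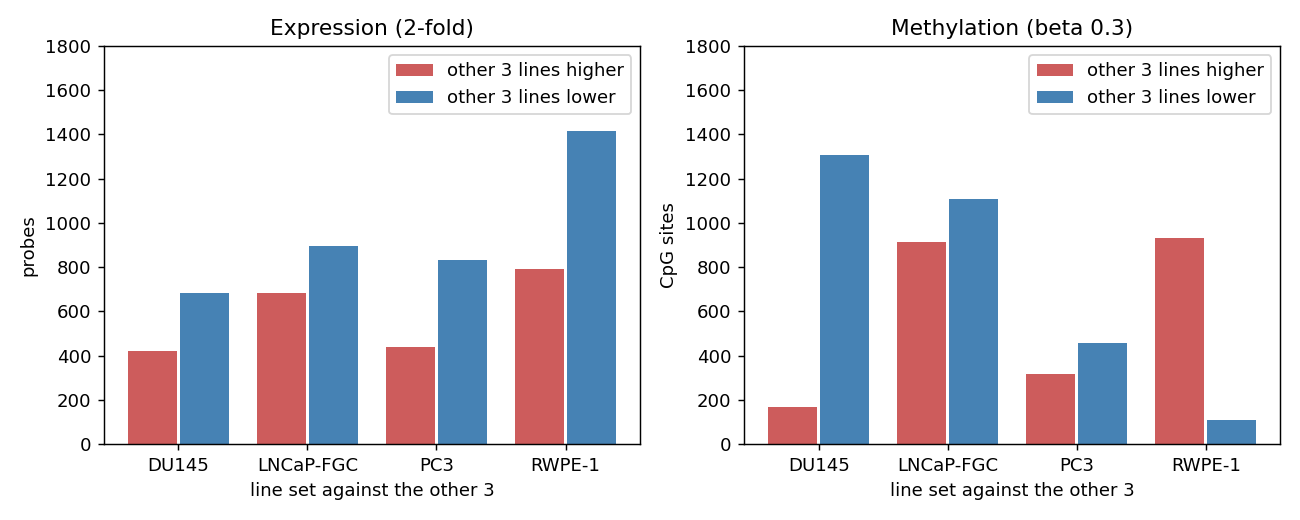
Number of expression probes (left, at least 2-fold) and CpG sites (right, beta difference of at least 0.3) at which the other 3 lines were all higher (red) or all lower (blue) than the line named on the x axis, 1 array per line. RWPE-1 stands apart at the most probes, 2208, and LNCaP-FGC at the most sites, 2021.

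Since the control was a single line, the shared differences were compared with those obtained when each cancer line in turn was set against the other 3. In expression RWPE-1 stood apart most, with 2208 probes (794 with the others higher, 1414 with the others lower) against 1106 for DU145, 1579 for LNCaP-FGC and 1272 for PC3. In methylation it did not. LNCaP-FGC stood apart at 2021 sites, DU145 at 1477, RWPE-1 at 1040 and PC3 at 775. The 932 sites at which RWPE-1 was the low line compared with 912 at which LNCaP-FGC was, 319 for PC3 and 170 for DU145. The 108 sites at which RWPE-1 was the high line compared with 456 for PC3, 1109 for LNCaP-FGC and 1307 for DU145. With 4 lines there are only 4 such splits, too few for a test. The methylation counts with each cancer line set apart were not made on quantile-normalized betas. With RWPE-1 set apart, those betas gave 496 and 314 sites in place of 932 and 108, so the ranking of lines may depend on the scale of the arrays.

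The pairwise comparison of lines ranked them differently in the 2 assays. In expression the closest pair was DU145 and PC3, with a Pearson correlation across probes of 0.907 and 14.1% of probes differing at least 2-fold. By the number of probes differing 2-fold, RWPE-1 differed from every cancer line (18.2% to 19.6% of probes) more than any cancer line did from another (14.1% to 16.4%). The correlations did not separate the lines this way: Pearson's r was 0.867 for LNCaP-FGC and PC3 against 0.869 for DU145 and RWPE-1, and Spearman's rho was 0.739 and 0.753 for these pairs and 0.773 for PC3 and RWPE-1. In methylation the highest correlation across sites was between DU145 and RWPE-1, at 0.812, followed by DU145 and PC3 at 0.787 and PC3 and RWPE-1 at 0.773. The lowest were those of LNCaP-FGC with RWPE-1, at 0.676, and with DU145, at 0.682. By the number of sites differing by 0.3, PC3 and RWPE-1 were closest, at 14.7% of sites, and DU145 and LNCaP-FGC farthest apart, at 22.1%. Probes and sites are not independent replicates, and these correlations describe the 4 arrays of each assay.

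**Figure D3:**
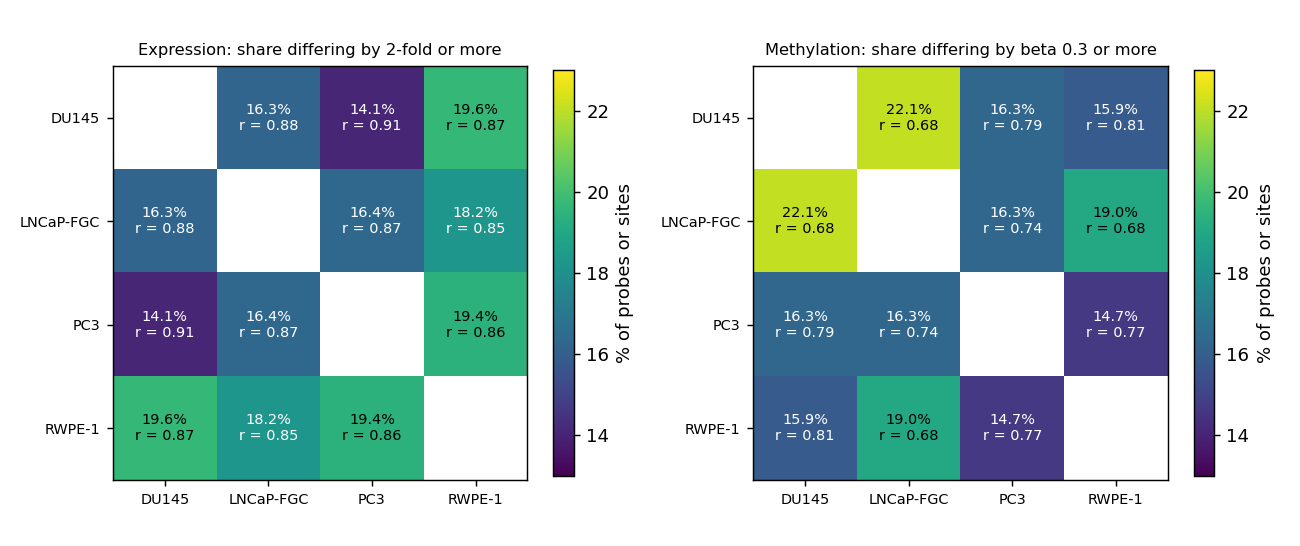
Share of expression probes differing at least 2-fold (left) and of CpG sites differing by a beta of at least 0.3 (right) for each pair of lines, with Pearson's r across probes or sites in each cell. RWPE-1 has the largest shares in expression, 18.2% to 19.6%, and LNCaP-FGC has the largest in methylation, up to 22.1%.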

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

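The tests of a bend in the DU145 scale, of LNCaP-FGC and PC3 without DU145, of other splits of the lines and of a property of RWPE-1, and the comparison of expression ratios between lines, were chosen after the results were seen.

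Some probes and sites differed from RWPE-1 in opposite directions in 2 cancer lines, by at least 2-fold or at least 0.3 in beta, and with 1 array per line the difference was not tested. In expression, 149 probes were higher in DU145 and lower in LNCaP-FGC, and 85 the reverse. For DU145 and PC3 the numbers were 64 and 61. For LNCaP-FGC and PC3 they were 67 and 174, so 174 probes were lower in LNCaP-FGC and higher in PC3 than in the control. In methylation, 165 sites were higher in DU145 and lower in LNCaP-FGC, and 65 the reverse. For DU145 and PC3 the numbers were 88 and 41, and for LNCaP-FGC and PC3 they were 38 and 45.

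Shared gains of methylation (932) outnumbered shared losses (108). For the 3 lines together, few sites being open to loss in RWPE-1 does not account for this in the deposited betas, since 4.14% of sites with room to gain did so against 1.27% of those with room to lose, a ratio of 3.27; for LNCaP-FGC and PC3 alone that ratio was 0.769, so the few sites open to loss could account for the excess of gains in those lines, and the pattern rests on DU145. A linear difference in array scale was argued against by a ratio of gains to losses of 8.31 after rescaling, while quantile normalization, which assumes no net difference, gave a gain share of 2.29% and a loss share of 3.15% and a ratio of those shares of 0.729. LNCaP-FGC, set against the other 3 lines, was the low line at 912 sites, so a property of the RWPE-1 line cannot be told apart from one of cancer with a single control line. Of the 4 splits, 1 gave as many as 932 (the highest other gave 912), and 4 splits are too few for a share under 0.05.

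DU145 had the highest or lowest beta of the 4 lines at 73.0% of sites. It was lowest at 81.0% of sites below 0.1 on all arrays and highest at 62.7% of sites above 0.8 on all, and outside those sites the share with DU145 extreme went from 65.7% to 52.0% after rescaling, which is consistent with a wider scale of that array. The number of sites at which DU145 was higher by 0.3 than each other line was 1307 before and 1237 after the same rescaling (94.6%), which argues against linear scale as the source of that number. A stretch away from intermediate values, acting alone, is argued against because DU145 lay 0.0847 above the other lines at sites of 0.2 to 0.4. It also lay 0.0811 above them at sites of 0.6 to 0.8, which a stretch would give too, so a stretch as a part of the cause is not excluded. An upward bend stays open for the gains: DU145's gain share was 1.10 times that of the other cancer lines at sites unmethylated in RWPE-1 and 1.67 times at intermediate sites. For DU145's few losses a bend and a difference between the lines both stay open: 61 sites methylated in RWPE-1 lay below 0.3 in DU145, 30.4% of the mean number below 0.2 in LNCaP-FGC (274) and PC3 (127), but with quantile-normalized betas its losses went from 21.3% to 45.1% of the other lines' mean at methylated sites (95% interval 39.7 to 51.3, counting error only) and from 36.4% to 67.8% at intermediate sites.

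Probes lower in all 3 cancer lines (1414) outnumbered those higher (794), a ratio of 1.78. The ratio was 1.61 with DU145 set apart, 1.31 with LNCaP-FGC and 1.88 with PC3, so a candidate explanation is that probes high in a single line are commoner than probes low in a single line, whichever line it is. Normalization stays open in part: the lowest ratio over the alternatives was 1.25, with median scaling (95% interval 1.15 to 1.36, counting error only), where the ratios of the other lines ran from 1.08 to 3.88. With RWPE-1 as the high line, 1 of the 4 splits gave as many as 1414 probes, the highest other being 895, and 4 splits are too few for a share under 0.05. That gap depended on the normalization: with median scaling, RWPE-1 was the high line at 1241 probes and PC3 at 1219.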

How the results depend on the processing

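Rescaled betas were tried only after the data were seen. The counts of 0 past the test held in expression under every alternative run except a variance trend with intensity, which called 28 probes, and in methylation under all except the test on beta, which called 70 sites. In methylation a held count of 0 shows no stability, since on simulated data the test on log2(beta / (1 - beta)) recovered 0% of planted differences of up to 6. The calls of the test on beta all lay just under its threshold. Moving the size threshold moved the counts. At 1.5-fold, 1931 probes were higher and 2582 lower in all 3 cancer lines, with 5930 higher and 5633 lower in DU145, 5622 and 5388 in LNCaP-FGC and 5824 and 5317 in PC3. At 4-fold these were 107 and 351, 832 and 1106, 843 and 1059, and 855 and 1120. At a beta difference of 0.2, shared gains were 1402 and shared losses 211, with 796 losses in DU145 and 1950 in PC3. At 0.5 they were 350 and 26, with 1970 gains and 171 losses in DU145, 1923 and 914 in LNCaP-FGC and 1400 and 499 in PC3. Quantile-normalized betas gave 496 shared gains and 314 shared losses, and 1758 gains and 1369 losses in DU145, because the method removes net differences between arrays. Leaving out each cancer line left 1222 to 1529 probes higher in the remaining lines, 1439 to 1641 sites gained and 179 to 709 lost, the last without DU145; with 1 line fewer to pass, counts can only grow. Of 125 values of counts under alternatives, 82 stayed within 1.5 times, among them all those for background correction, median scaling, the authors' log2 values, the offset and rescaled betas. These 82 include 9 expression and 6 methylation counts of 0 past the test, to which a factor does not apply. They also include the shared counts under the filters on dim probes. The filters on dim probes removed none of the shared differences, so they test nothing there. The differences at named probes and sites kept their direction in 56 of 56 alternatives, 4 of which moved them by more than the spread between lines. Leaving out a cancer line could not reverse them, since they were chosen for a shared direction in all 3. The filters on dim probes left them unchanged. The direction was therefore open to change only under the other alternatives. The causes were not tested beyond what is stated. One probe per gene, removal of sex-chromosome sites, gene lists and the match by gene were not run, for want of gene names. No array signals behind the betas were used, so their precision per site is unknown.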

Other observations

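The comparisons here were chosen after the data were seen. Sites intermediate in 3 lines were looked up in the remaining one. At 98 sites between 0.4 and 0.6 in LNCaP-FGC, PC3 and RWPE-1, the DU145 median was 0.654 and 58.2% of sites lay above 0.6. At 74 sites in that range in the 3 cancer lines, the RWPE-1 median was 0.449, and 43.2% lay below 0.4. For LNCaP-FGC the median at 73 such sites was 0.453, with 37.0% below 0.4, and for PC3 it was 0.503 at 50 sites, with 22.0% below 0.4.

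Of 17982 sites unmethylated in RWPE-1, 760 (4.23%) were above 0.8 in DU145, 870 (4.84%) in LNCaP-FGC and 533 (2.96%) in PC3. Of 3645 sites methylated in RWPE-1, 42 (1.15%) were below 0.2 in DU145, 274 (7.52%) in LNCaP-FGC and 127 (3.48%) in PC3. The first number was the higher in each line, but the first share was the higher in DU145 alone. In expression, Spearman's rho across probes was 0.741, 0.739 and 0.729 for LNCaP-FGC with DU145, PC3 and RWPE-1, 0.753 and 0.773 for RWPE-1 with DU145 and PC3, and 0.791 for DU145 and PC3. By this measure LNCaP-FGC had the lowest values in expression, where 2-fold counts set RWPE-1 farthest apart. In methylation rho was highest for DU145 and RWPE-1, at 0.852. With 6 pairs of 4 lines, no relation between the assays was tested.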
